A study of Mus musculus with 13 samples.

How the data were processed

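Aortic miRNA was profiled in male mice of the C57/BL6 strain on single-colour arrays with biotin-labelled RNA. The labels give a genotype and an age class for each of 13 samples, and the series design gives the ages, 3 to 4 months for young mice and 12 months for aged mice. MR-intact mice carry a working mineralocorticoid receptor (MR), the steroid receptor for aldosterone, and knockout mice lack it in smooth muscle cells. Young MR-intact, young knockout and aged knockout aortas had n = 3 arrays each, and aged MR-intact aortas had n = 4. Each sample is titled by a number of its own, and no label states that each array came from a different mouse, so p-values measure the spread between these samples. The labels name no batch, scan date or RNA quality value.

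The deposited table held log2 values of 1412 probe sets, which lay between 0.07 and 14.38. RMA, the affy package and limma are listed without versions, per the submitters' processing notes, and the array design, the annotation and the filters are not given in the sources used here. The log base is not stated in the table and was taken as 2 from the range of the values. Of the probe sets, 717 carried a mouse mature miRNA name, 690 a precursor name and 5 a name from an older release of the miRNA catalogue. The 717 mature probe sets entered the tests, and the others were used only for a background and as an alternative. No values were reprocessed from scanner files, and no depth applies to arrays, so the number of arrays and the signal over background limit the precision. miRNA names are those of the array, in which a star marks the minor arm of a precursor and miR-1 stands for miR-1a. Close family members, such as those of let-7 or miR-133a and miR-133b, can share hybridisation signal. A mouse gene of the same name was sought in RefSeq genes of assembly GRCm38.p6 for names only, and 675 of the 717 mature probe sets had one and 42 had none.

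The tests and the lists were fixed before the data were examined. One limma model (version 3.58.1, R 4.3.3) with a mean for each of the 4 groups was fitted to the deposited log2 values, with eBayes without trend and not robust. From it came 7 contrasts, which were age in MR-intact aortas, age in knockout aortas, their mean, knockout in young aortas, knockout in aged aortas, their mean, and the interaction of age and genotype. Adjusted p-values are Benjamini-Hochberg values from limma over the 717 probe sets, and a miRNA was called at an adjusted p under 0.05. In the age and knockout contrasts a positive value means a higher level in aged aortas or in knockout aortas. The interaction is the change with age in knockout aortas minus that in MR-intact aortas. On simulated data with 200 changed miRNAs the same fit recovered 79.1% of changes of 1 log2 unit and 94.0% of changes of 2 log2 units for age averaged over genotypes. For knockout in aged aortas it recovered 82.1% and 91.0%, for knockout in young aortas 56.7% and 86.6%, and for the interaction 49.3% and 79.1%. The changed miRNAs were drawn at random from all 717, of which 523 had a mean below 2, and the simulated noise was independent. These shares therefore do not give the power for miRNAs above background or for a contrast with few changes.

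The miRNAs named below are the 10 with the largest positive and the 10 with the largest negative change among those called in a contrast, or the smallest p-values where fewer than 10 were called. Up to 4 members of each list with the smallest p, and miR-155, miR-143, miR-145, miR-126-3p, miR-21, miR-34a, miR-29b, miR-451, miR-122, miR-1 and miR-133a, were named in addition. No probe set carried the name of miR-155-3p. The 17 lists covered smooth muscle regulators, striated muscle, endothelium, leukocytes, erythroid cells, adipose tissue, neurons, liver, epithelium, vascular ageing, fibrosis, the Dlk1-Dio3 cluster, the miR-17~92 clusters, the let-7 family, the miR-15 and miR-16 family, the Sfmbt2 cluster and miRNAs that target or respond to the MR pathway. The 16 lists with at least 3 probe sets were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a contrast. The alternatives were camera with an estimated correlation and fry, which tests whether a list moves on balance in 1 direction without comparing it with other miRNAs.

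An array's background was set, after the data were seen, at the 99th percentile of its 690 precursor probe sets. Where a miRNA was at or below background on all arrays of its dimmer group, its change is given as at least N-fold. This bound sets the mean of the brighter group against the lowest mature value above background on each dim array, averaged over those arrays. Numbers of probe sets above background were compared with exact two-sided permutation tests. Alternatives were another spread prior, filters on dim probe sets, median centring, a repeat of quantile normalization over the mature probe sets, array weights, other thresholds, all 1412 probe sets, and leaving out each array in turn. The repeated quantile normalization gives the mature probe sets of all arrays the same distribution. It therefore shrinks a fall shared by many miRNAs whatever its source, and cannot tell a change with age from one of processing. Leaving out 3 doubted arrays together and the number of probe sets above background as a covariate were added after the data were seen. So was leaving out names without a RefSeq gene.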

Results

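Levels of the mature mouse miRNA probe sets were measured in whole aortas of young and aged mice with an intact mineralocorticoid receptor (MR) or with MR deleted in smooth muscle cells. The study asked which vascular miRNAs change with age and whether the smooth muscle MR takes part in that change. The MR transcript is not measured on a miRNA array, so the deletion itself could not be checked. The 13 arrays correlated with each other at r = 0.762 to 0.993 over the mature probe sets, and no pair was identical.

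The smooth muscle miRNAs miR-143 and miR-145 and the endothelial miR-126-3p were among the bright signals in every group, with means in young MR-intact aortas of 12.2 ± 0.14, 12.81 ± 0.26 and 10.44 ± 0.19 (log2, SD, n = 3). Aged aortas had far fewer miRNAs above the array background than young aortas. The number was 248 ± 20.5 (SD, n = 3) in young MR-intact, 229 ± 40.4 (n = 3) in young knockout, 136 ± 21.7 (n = 4) in aged MR-intact and 116 ± 22.9 (n = 3) in aged knockout aortas. All 7 aged arrays lay below all 6 young arrays (exact two-sided permutation p = 0.000583, the smallest that 1716 splits allow, and 0.00291 after Benjamini-Hochberg adjustment over 5 comparisons). Within MR-intact aortas the exact p was 0.0286 (adjusted 0.0714) and within knockout aortas 0.1 (adjusted 0.167), each the smallest its splits allow, and neither passed. Between genotypes the exact p was 0.7 in young and 0.429 in aged aortas. The first principal component held 64.9% of the variance and followed age. On it, aged MR-intact replicate 2 lay towards the young arrays, young knockout replicate 3 towards the aged arrays, and aged knockout replicate 2 apart from the rest. No label gives a batch, so age and any difference in array processing between ages cannot be told apart.

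**Figure D1:**
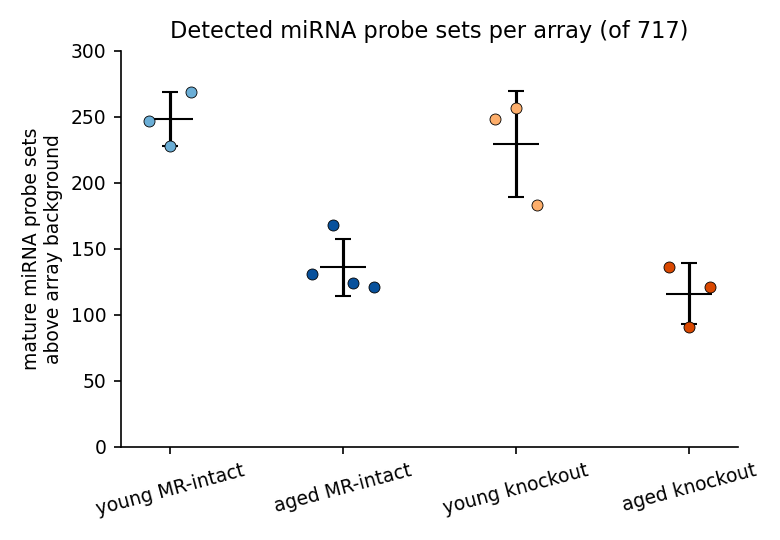
Number of mature miRNA probe sets above the array background (y axis, count) on each array of the 4 groups (x axis), with the group mean and SD as bars. The aged arrays lie between 91 and 168 and the young arrays between 183 and 269.

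The first comparison asked what age changed in MR-intact aortas. Most of what changed was lower in aged vessels, and the drops included miR-196a, which lies in the Hox clusters, the muscle miRNA miR-1 and members of the imprinted Dlk1-Dio3 cluster. miR-196a averaged 6.02 ± 0.29 in young and 1.04 ± 0.33 in aged aortas (log2, SD), a level at least 14.5-fold lower (limma adjusted p = 1.66e-06). The cluster members miR-127, miR-541 and miR-382 fell by 4.82, 4.27 and 4.27 on the log2 scale (SE 1.004, 0.845 and 0.54), with limma adjusted p of 0.0106, 0.00964 and 0.000919. miR-1 fell by 4.42 (SE 0.52, adjusted p = 0.00052). miR-106b-star, miR-342-3p, miR-199a-5p, miR-182 and miR-187 completed the 10 largest falls, between 4.06 and 3.91 log2 units.

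Few miRNAs rose with age in MR-intact aortas. miR-466f-3p rose by 3.32 log2 units (SE 0.62, limma adjusted p = 0.00683) and miR-1893 by 2.12 (SE 0.46, adjusted p = 0.0128). miR-2146, miR-705 and miR-2133 rose by 1.94, 1.93 and 1.66 log2 units, but miR-2146 and miR-2133 had no mouse miRNA gene of that name in RefSeq. let-7f-star, miR-599, miR-499 and miR-376a-star were called higher too, but none was above background on any MR-intact array, so no change in level is given. In total 107 miRNAs passed, 9 higher and 98 lower. The median of those lower was -2.52 log2, and -0.947 for the same miRNAs after repeated quantile normalization. Of the 98, 61 were at background on all aged arrays.

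The number called in MR-intact aortas was 162 without the 3 arrays that stood apart on the first component, 26 (8 higher and 18 lower) after a repeated quantile normalization of the mature probe sets, and 1 with the number of probe sets above background as a covariate. It was 68, 63 and 57 without aged MR-intact replicates 1, 3 and 4, and 60 and 43 without young MR-intact replicates 1 and 3. Among the arrays that stood apart, aged MR-intact replicate 2 and young knockout replicate 3 lay towards the other age on the first component, which followed age. Leaving them out therefore favours higher counts in this and the other age contrasts.

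The same question in knockout aortas gave largely the same picture. miR-206, a miRNA of skeletal muscle, averaged 6.66 in young and 0.99 in aged knockout aortas, at least 24.4-fold lower (limma adjusted p = 0.00179). The Dlk1-Dio3 members miR-541 and miR-382 were at least 17.4-fold and 16-fold lower (adjusted p = 0.00495 and 0.000531), and miR-127 and miR-379 fell by 5.29 and 4.39 log2 units (SE 1.07 and 1.03). miR-187 was at least 14.6-fold and miR-196a at least 12.4-fold lower, and miR-1839-5p, miR-676 and miR-199a-5p fell by 4.74, 4.54 and 4.37 log2 units. miR-222, which promotes growth of smooth muscle cells, fell by 3.90 (SE 1.06, adjusted p = 0.0431), but its aged knockout arrays read 6.90, 1.25 and 2.98.

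The probe sets that rose in knockout aortas were miR-705 by 2.26 log2 units, miR-2146 by 2.11, miR-2135 by 2.06, miR-2133 by 2.02, miR-2145 by 1.87 and miR-690 by 1.47. Of these, miR-2146, miR-2135, miR-2133 and miR-2145 had no mouse miRNA gene of that name in RefSeq. miR-465c-5p and miR-1274a were called higher too, but neither was above background on any knockout array. In total 79 miRNAs passed in limma, 8 higher and 71 lower, with a median of -3.04 log2 among those lower, 50 of which were at background on all aged arrays. After repeated quantile normalization the median of the same 71 was -1.50. The number called was 125 without the 3 arrays that stood apart, 30 (10 higher and 20 lower) after repeated quantile normalization, 2 with the number of probe sets above background as a covariate and 29 with only the knockout arrays in the fit. It was 28 and 29 without aged knockout replicates 2 and 3, 25, 26 and 134 without young knockout replicates 1, 2 and 3, and 50 without young MR-intact replicate 1.

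Age effects in the 2 genotypes ran closely together. The changes with age correlated at r = 0.852 and rho = 0.727 across all miRNAs tested, which are not independent replicates, and at r = 0.803 over the 307 miRNAs above background on any array. Both fits called 61 miRNAs, 58 lower in both and 3 higher in both, where independent lists would share 9.70 and 0.10 (one-sided Fisher's exact p = 7.68e-46 and 7.45e-05). That test counts miRNAs as independent and ignores their level. Averaged over genotypes, 101 of 124 miRNAs with a young level between 2 and 6 fell, against 26 of 486 below 2. Its p-values therefore do not measure the agreement between genotypes. The 3 higher in both were miR-705 and the probe sets miR-2146 and miR-2133, which had no RefSeq gene of that name. None changed in opposite directions. Of the 107 called in MR-intact aortas, 105 had the same sign in knockout aortas.

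**Figure D2:**
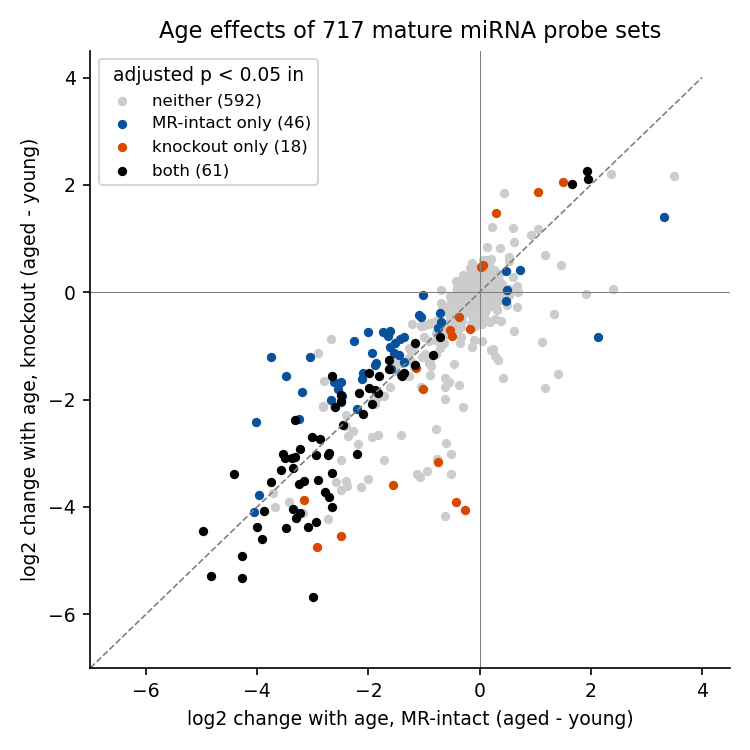
Change with age of each mature miRNA in MR-intact aortas (x axis, log2, aged minus young) against the change in knockout aortas (y axis, log2, aged minus young). Black points are the 61 miRNAs called in both genotypes, and the dashed line marks equal changes.

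Averaged over genotypes, 175 miRNAs passed in limma, 15 higher and 160 lower in aged aortas. By the deposited values the largest falls were in miR-127 (-5.06 log2, SE 0.74), miR-541 (-4.80, SE 0.62), miR-196a (-4.72, SE 0.20) and miR-382 (-4.59, SE 0.40), and all 7 aged arrays lay below all 6 young arrays for each. miR-196a was at background on all aged arrays, so only a fall of at least 13.4-fold is known. The other members of this group were at background on most aged arrays, so these sizes and their order are limited by background. Next came miR-206, miR-187, miR-199a-5p, miR-106b-star, miR-133a and miR-379, at -4.33 to -3.94 log2. The largest rises were in miR-1931 (2.83 log2 units, SE 0.86, adjusted p = 0.0331), miR-466f-3p (2.37), miR-705 (2.09), miR-2146 (2.03), miR-2133 (1.84), miR-2135 (1.77) and miR-2145 (1.46), followed by miR-455, miR-2861 and miR-690 (1.12, 1.0 and 0.89). Among them miR-2146, miR-2133, miR-2135 and miR-2145 had no mouse miRNA gene of that name in RefSeq. Classed by level in young aortas, which also enters the change, 101 of 124 miRNAs between 2 and 6, 23 of 77 between 6 and 10 and 10 of 30 above 10 were lower. Of the 175, 5 called higher and 8 called lower were above background on no array. With repeated quantile normalization 69 miRNAs passed, 28 higher and 41 lower, and with the number of probe sets above background as a covariate 2 passed; 209 passed without the 3 arrays that stood apart.

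**Figure D3:**
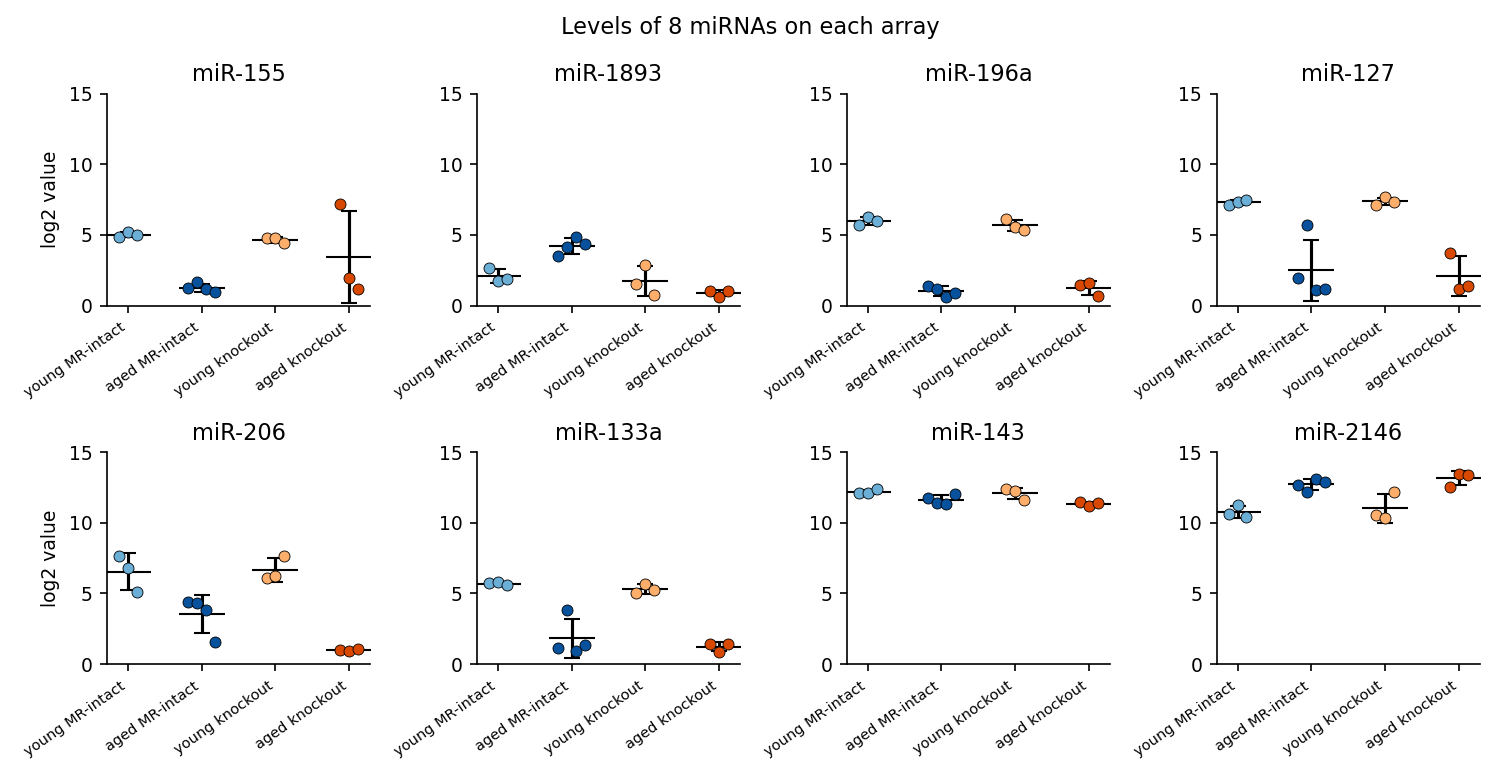
Levels of 8 miRNAs on each array (y axis, log2 value) in the 4 groups (x axis), with group mean and SD as bars. miR-196a, miR-127, miR-206 and miR-133a are lower and miR-2146 is higher in aged aortas of both genotypes, miR-155 is high on 1 aged knockout array, and miR-1893 is high in aged MR-intact aortas. miR-2146 has no mouse miRNA gene of that name in RefSeq.

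Of the 8 striated muscle probe sets, 4 fell with age averaged over genotypes, and 5 adjusted over the list alone. They were miR-1, miR-133a, miR-133b and miR-206, which control muscle differentiation, and the first of these fell by 3.90 log2 units (SE 0.38, limma adjusted p = 6.5e-05). Among 75 probe sets of the Dlk1-Dio3 cluster, which is expressed from the maternal chromosome, 20 were called lower and 2 higher (21 and 2 adjusted over the list alone), although only 24 were above background on any array, and the 2 called higher were not among them. miR-329 was at least 5.39-fold and miR-433 at least 2.21-fold lower in aged aortas. In the let-7 family 9 of 17 were called lower and 1 higher, the same numbers as adjusted over the list alone. The very abundant let-7c fell by 1.01 log2 units (SE 0.14) and miR-98 by 2.85 (SE 0.27), a value that turned to 0.14 higher after repeated quantile normalization, while let-7d-star was at least 3.22-fold lower, and let-7f-star, called higher, was above background on no array.

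The fibrosis and extracellular matrix list had 13 of 26 probe sets lower and none higher with age, and 16 lower adjusted over the list alone. It was the 1 list that camera called against other miRNAs (adjusted p = 0.00319), and with an estimated correlation the adjusted p was 0.631. Over probe sets above the median level the list was not called (adjusted p = 0.523), and among miRNAs above 2 in young aortas 55% of its 20 members fell against 58.3% of 211 others. Over 4 classes of young level, with all 26 members, the odds ratio of the list was 1.545 (exact Mantel-Haenszel p = 0.434, adjusted 0.868). This exact test counts miRNAs as independent. Its members miR-30b-star and miR-30c-1-star were at least 1.85-fold and 1.88-fold lower, and miR-133a and miR-199a-5p, named above, also belong to it. The list was called within each genotype too, with 6 of 26 lower in MR-intact aortas (12 adjusted over the list alone, adjusted p = 0.00348, 0.629 with an estimated correlation and 0.295 above the median level). In knockout aortas 4 were lower, and 4 adjusted over the list alone (adjusted p = 0.0373, 0.746 with an estimated correlation and 0.875 above the median level). The call in knockout aortas was lost in 4 of the 13 fits that leave out an array, with an adjusted p of up to 0.396 without aged knockout replicate 2.

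Among regulators of vascular smooth muscle 3 of 20 fell averaged over genotypes, and 6 adjusted over the list alone. Of the 15 above 2 in young aortas 20% fell, against 60.65% of 216 other miRNAs, shares that are not matched on level. Over the 4 classes of young level, with all 20 members, the odds ratio was 0.315 and did not pass (exact Mantel-Haenszel p = 0.147, adjusted 0.634). miR-143 and miR-145, which maintain the contractile state, fell by 0.67 and 0.48 log2 units (SE 0.15 and 0.12, limma adjusted p = 0.00875 and 0.0141), and the third was miR-31-star, at background on all aged arrays, whose value turned to 0.05 after repeated quantile normalization. In the vascular ageing list 6 of 21 fell, and 6 adjusted over the list alone. Of its 10 members above 2 in young aortas 50% fell, against 58.37% of 221 others. Its odds ratio over the same classes was 1.166 and did not pass. miR-181b fell by 3.74 log2 units and miR-34a, a target of p53, by 2.48 (adjusted p = 0.0207), and miR-22-star, miR-29b-star and miR-29c were at least 1.41-fold, 1.02-fold and 1.29-fold lower. miR-21 and miR-29b did not pass, at -2.37 (adjusted p = 0.0583) and -0.47 (adjusted p = 0.173).

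Markers of other cell types mostly moved down with age or did not pass. The leukocyte list had 6 of 14 lower (7 adjusted over the list alone), among them miR-342-3p, miR-146b and miR-132, at -3.22, -1.85 and -2.82 log2, and miR-342-5p, at least 2.04-fold lower. In the adipose list miR-182 fell by 3.88 log2 units and miR-183 was at least 1.66-fold lower, while miR-455, a promoter of brown adipocyte fate, rose, so that 3 of 14 were lower and 1 higher (4 and 2 adjusted over the list alone). Of 13 neuronal probe sets miR-128 and miR-138 were at least 2.32-fold and 1.33-fold lower (miR-138 turned to 0.12 higher after repeated quantile normalization), of 3 hepatic ones miR-192 and miR-194 fell, and of 10 epithelial ones miR-200c fell by 3.34 log2 units; adjusted over the list alone the numbers were 2, 2 and 1. None of the 3 erythroid probe sets passed (1 lower adjusted over the list alone), with miR-451 at -2.51 (adjusted p = 0.0503), and the liver miRNA miR-122 was at -2.03 (adjusted p = 0.216). The 2 endothelial probe sets, too few for a list test, did not pass either, with miR-126-3p at -0.08 (adjusted p = 0.863), a value whose sign turned to 0.02 after median centring.

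In the miR-17~92 clusters 7 of 21 probe sets fell (7 lower and 1 higher adjusted over the list alone), with miR-17-star at least 6.55-fold lower, miR-93-star at least 1.5-fold lower, and miR-18a at -1.825 log2 (0.46 after repeated quantile normalization). In the miR-15 and miR-16 family 2 of 10 fell (4 adjusted over the list alone), namely miR-497 by 3.20 log2 units and miR-322, which was at background on all aged arrays. In the Sfmbt2 cluster 7 of 54 were called lower and 1 higher, the same numbers as adjusted over the list alone, and miR-669c stood at -2.58 log2, while miR-466c-5p was at background on all aged arrays. Of 16 miRNAs that target or respond to the MR pathway, miR-27a-star was called lower (adjusted p = 0.0475) and was at background on all aged arrays, and none passed adjusted over the list alone. The neuronal, epithelial, Sfmbt2 and MR lists had a mean below 0 while camera placed them above other miRNAs, with adjusted p from 0.364 to 0.929, and the epithelial median was 0.05. fry called 11 of the 16 lists, all of them lower in aged aortas.

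The knockout comparisons asked what loss of the smooth muscle MR changed at each age. In young aortas no miRNA passed in limma, and 17 had an unadjusted p under 0.05. miR-466e-3p had the smallest, with 3.11 in MR-intact and 1.95 in knockout aortas (difference -1.15, SE 0.28, adjusted p = 1), followed by miR-1965, miR-154, miR-15a-star and miR-499. Of these, miR-1965 had no mouse miRNA gene of that name in RefSeq, and miR-15a-star and miR-499 were above background on no young array. miR-143 and miR-145 differed by -0.12 and -0.05. The miR-15 and miR-16 family was the 1 list that camera called, placed lower in knockout aortas with a median of -0.31 and an adjusted p of 0.0167, but no member was called over all miRNAs or adjusted over the list alone. With an estimated correlation its adjusted p was 0.79, above the median level 0.234, and the call was lost in 3 of the 13 fits that leave out an array, with an adjusted p of up to 0.2 without young knockout replicate 2.

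In aged aortas 1 miRNA passed. miR-1893 averaged 4.22 ± 0.56 (SD, n = 4) in MR-intact and 0.90 ± 0.22 (n = 3) in knockout aortas, at least 4.51-fold lower (difference -3.33, SE 0.46, limma adjusted p = 0.0149), and all 3 knockout arrays lay below all 4 MR-intact arrays. In all, 48 had an unadjusted p under 0.05. Of those not passing, miR-222 and miR-193-star differed by -3.49 and -3.60 (adjusted p = 0.41 for each), and miR-690 by 1.10, while let-7a-star, miR-703, miR-582-3p, miR-465c-5p and miR-1938 were above background on no aged array. The call of miR-1893 was lost without aged MR-intact replicate 2, 3 or 4 or aged knockout replicate 2 or 3, with an adjusted p of up to 0.115. Without aged knockout replicate 1 the number called was 11, 1 higher and 10 lower, with miR-185 and miR-222 at -5.69 and -5.08 (adjusted p = 4.06e-09 and 0.000217).

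Averaged over ages no miRNA passed for knockout in limma, and 35 had an unadjusted p under 0.05. miR-1893 came first at -1.85 (SE 0.34, adjusted p = 0.156), then miR-466e-3p at -0.74 and miR-291b-5p, where miR-1893 was at background on all aged knockout arrays and miR-466e-3p on all aged arrays, so these sizes are limited by background. let-7f and miR-98 differed by -0.39 and -0.82 and did not pass. No list was called by camera for knockout in aged aortas or averaged over ages, with a smallest adjusted p of 0.484 and 0.0974. Without aged knockout replicate 1 the number called was 4.

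Whether the knockout altered the age effect was tested by the interaction. No miRNA passed in limma, and 28 had an unadjusted p under 0.05. miR-1893 again came first, as it rose with age in MR-intact aortas by 2.12 log2 units and was at background on all aged knockout arrays (adjusted p = 0.325 for age in knockout aortas). Its interaction of -2.95 (SE 0.68, unadjusted p = 0.00123, adjusted p = 0.879) is limited by background and is not an exact size. miR-499 and miR-703, above background on no array, and miR-466g, at background on all aged knockout arrays, followed (adjusted p = 0.989 for each). No list was called, the smallest adjusted p being 0.547. Without aged knockout replicate 1 the interaction called 4 miRNAs, namely miR-185, miR-222, miR-574-3p and miR-193-star, at -5.69, -5.08, -3.65 and -5.35 (adjusted p = 8.62e-08, 0.00357, 0.00357 and 0.0161); miR-185 and miR-574-3p were named after their values were seen.

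The change with age in MR-intact aortas and the knockout effect in aged aortas share the aged MR-intact arrays. A knockout that undid the age effect would give a negative correlation. Across miRNAs the correlation was r = 0.147 and the covariance 0.0986. Simulated unchanged groups gave r = -0.424 and a covariance of -0.0918, a difference in covariance of 0.190. Unchanged groups hold no age effect, and an age effect widens the spread of the change with age. The r of -0.424 is therefore not the value to be had here without a knockout effect, and the 2 r values are no like comparison. With the aged MR-intact arrays split into 2 and 2, r averaged 0.208 over 6 splits and lay between -0.104 and 0.480. The sign depended on single arrays, with r = -0.168 without aged MR-intact replicate 2 and -0.0425 without aged knockout replicate 2.

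miR-155, an miRNA of immune and vascular cells that the study's later publication followed up and so was chosen on these samples, was lower in aged than in young MR-intact aortas. It averaged 5.0 ± 0.18 (SD, n = 3) in young and 1.25 ± 0.29 (n = 4) in aged MR-intact aortas, at least 7.20-fold lower (limma adjusted p = 0.0426, and 0.418 after repeated quantile normalization). In knockout aortas it averaged 4.65 ± 0.22 (n = 3) in young and 3.45 ± 3.26 (n = 3) in aged mice, a difference of -1.20 (SE 1.17, adjusted p = 0.569) that turned to 1.53 after repeated quantile normalization. The aged knockout arrays read 7.18, 1.99 and 1.17, so that 1 array lay above all young arrays and the others near the aged MR-intact level. That array had 136 miRNAs above background against 91 and 121 on the others. The mean in aged knockout aortas was at least 2.45-fold that of aged MR-intact aortas, all at background, without passing (adjusted p = 0.759), and this bound rested on 1 array, as the difference was 0.33 without aged knockout replicate 1. The age effects of the genotypes differed by 2.55 (SE 1.60, adjusted p = 0.989), a size limited by the same background. Without aged knockout replicate 1 miR-155 was lower with age in knockout aortas as well, by -3.07 (adjusted p = 8.56e-05). In MR-intact aortas the adjusted p rose to between 0.0546 and 0.132 in the 9 fits that leave out any 1 of the MR-intact arrays or young knockout replicate 1 or 2.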

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

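The tests of array-wide signal, of uniform scaling and of aged knockout replicate 1 were chosen after the results were seen, and the test of the rising probe sets was written before. For 12 of 98 named miRNAs 1 aged MR-intact array lay far from the other 3, which chance gives in about 1 in 20 groups, and 10 of the 12 were on replicate 2. That array read 5.42 for miR-541, 5.84 for miR-187, 4.98 for miR-30c-2-star, 6.02 for miR-106b-star, 3.84 for miR-133a, 5.93 for miR-199a-5p, 6.46 for miR-182 and 5.8 for miR-342-3p, all above the others. It read 6.95 for miR-466f-3p and 0.52 for miR-146b-star, both below the others. miR-22-star was 1.15 on replicate 4 and miR-669c 4.94 on replicate 3. Outside the mature probe sets, higher levels in aged aortas appeared for the precursors of miR-188 and miR-717, by 0.298 and 0.318 log2 units near the background, and for miR-805 of an older catalogue release, by 2.3 log2 units. Others were called lower, also at low levels, such as the precursors of miR-143 (-0.912), miR-181a-2 (-0.779) and miR-145 (-0.504), and miR-699 of the older release (-0.735).

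Most miRNAs that changed with age were lower in aged aortas. An equal log2 shift of all miRNAs is argued against, but not one that varies with level. Classed by mean level, the median change was -2.52 between 2 and 6, -0.901 between 6 and 10 and -0.204 above 10. Classed by young level, which also enters the change, it was -2.0, -1.77 and -0.246. The median of -2.02 for those called lower, set against -0.204 in the test, is no like comparison, as these were chosen for their fall. Array-wide differences in miRNA signal may contribute, since the leading component of the differences between arrays of the same group (40.8% of that variance) correlated with the age effect across miRNAs (size of r = 0.683). The number of probe sets above background as a covariate tells nothing on this, since it counts the falls themselves (82 of the 160 were at background on all aged arrays) and the 4 groups explain 86.2% of it; with it 92 of the 175 calls turned sign and their median went from -1.85 to -0.0097 (median SE 0.712). Age itself stays open as an untested biological explanation, and it cannot be separated from processing without batch labels.

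Of the 9 bright probe sets that rose with age 4 (miR-2133, miR-2135, miR-2145 and miR-2146) had no mouse miRNA gene of their name in RefSeq, against 7 of the 73 other bright ones (one-sided Fisher's exact p = 0.0163). These probe sets may read RNA that takes a larger share where fewer miRNAs are above background. Within groups the mean of the 11 bright probe sets without a name correlated with the number above background at r = -0.788 (exact permutation p = 0.0152), and at r = -0.625 without the 2 farthest arrays. The 71 bright ones with a name went the other way (r = 0.508, exact permutation p = 0.00135). A change of these miRNAs with age was not excluded.

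Several miRNAs, miR-155 among them, were higher on aged knockout replicate 1 than on the other aged knockout arrays. A higher signal of much of the array may be 1 source, since 77 miRNAs with a young level between 6 and 10 were higher on it by a median of 2.12 (median absolute deviation 2.44; 3.11 against replicate 2 and 0.68 against replicate 3), and those above 10 by 0.345. Tests on miRNAs of the young level of miR-155 (median 0.223) and on the 160 called lower with age (median 0.20) came first and gave small differences. Both were dropped after these values were seen. Of the 48 miRNAs of like level 27 were at background on all aged knockout arrays, and no such reason is given for the 160. For miR-155, which differed by 5.60, a higher signal is argued against as the whole source. The 7 arrays with more probe sets above background, a stand-in for signal, read 1.64 to 5.2 (SD over the young arrays 0.264) against 7.18 on this one. A wrong genotype label is argued against for miR-155, since the aged MR-intact arrays read 1.25, 1.64, 1.16 and 0.95. For the other miRNAs a wrong genotype label stays open, and a difference between animals stays open for all of them. Of the 11 miRNAs called in fits without this array 10 lay nearer to aged MR-intact on it and miR-1893 did not. The other 6 aged arrays, each left out in turn, lay nearer to the other genotype for 3 to 7 of the 11 miRNAs with the smallest p. The signal of aged knockout replicate 1 differs too.

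In MR-intact aortas 1 of the 35 splits of the arrays gave as many as 107 calls, the real one, and the highest other gave 65. That is the smallest share 35 splits allow, and it was not adjusted over the contrasts. It argues against chance without excluding it. Averaged over genotypes 1 of 100 drawn splits gave 175, with 14 as the highest other, which argues against chance as well. For age in knockout aortas (79, highest other 1, 1 of 10 splits as large) the splits are too few. For knockout in aged aortas the splits do not argue against chance (1 call, 13 of 35 splits as many, highest other 4). With 0 calls every split gives as many, so the splits tell nothing for knockout in young aortas (10 of 10, highest other 2), knockout averaged over ages (100 of 100, highest other 2) and the interaction (100 of 100, highest other 3). In limma these 0 counts stood beside 17, 35 and 28 at an unadjusted p under 0.05 for young, averaged and interaction. The interaction splits exchanged genotypes within an age; exchanging arrays across ages, which was tried first, gave up to 58 calls.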

How the results depend on the processing

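The settings without 3 doubted arrays, with the number above background as a covariate, and without names lacking a RefSeq gene were chosen after the data were seen. The doubted arrays were those that stood apart on the first component, which followed age, so leaving them out favours higher age counts. No paired analysis was run because no label links arrays of different groups, and the replicate numbers used here only follow the order of the titles within a group. Some title numbers follow each other across genotypes within an age, and those of young and aged samples lie far apart. What they stand for was not examined. Signal over background limits the results, and the cause of the changes below was not tested. Of 139 calls of single miRNAs 40 kept direction and threshold in every setting except the covariate; among 4581 alternative values of 199 results 507 lost the threshold, 50 gained it and 18 turned sign. The covariate was first run for each miRNA too, and it turned 63 of the 199, 49 of them called; it was then limited to counts, so 13 results turned sign without it and 70 with it, and its single values are not listed.

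Counts for age in MR-intact aortas (107) were 58 over the top 25% by level, 26 with quantile normalization, 162 without the doubted arrays, 1 with the covariate, and 29 higher and 166 lower (2.0e+02 together) at unadjusted p under 0.05. In knockout aortas (79) they were 30 with quantile normalization, 165 with array weights, 50 over all probe sets, 125 without the doubted arrays, 2 with the covariate, 29 with only the groups compared, 135 at adjusted p under 0.1 and 202 unadjusted. Averaged (175) they were 105 over the top 25%, 69 with quantile normalization and 2 with the covariate. Of the calls, 30 of 107, 20 of 79 and 92 of 175 had the opposite sign with the covariate, which counts the falls themselves. Quantile normalization left 144 of the 160 averaged falls lower and 41 called, with a median of -0.645 against -2.02 in the main fit. As it gives all arrays the same distribution, smaller falls and more rises were built into it and tell nothing on their source. Median centring gave 35 higher and 147 lower.

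Knockout counts from limma were 17 (young, main 0), 48 (aged, main 1), 35 (average, main 0) and 28 (interaction, main 0) unadjusted, 3 in aged aortas without the doubted arrays, and 1 averaged with quantile normalization. Lists (4) were 0 with an estimated correlation, 25 with fry and 2 above the median level, where the Sfmbt2 list was placed higher in MR-intact and averaged (adjusted p = 0.0135 and 0.0242).

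With 1 array left out the ranges were 43 (without young MR-intact replicate 3) to 128 for age in MR-intact aortas, with 68, 63 and 57 without aged MR-intact replicates 1, 3 and 4 and 60 without young MR-intact replicate 1. In knockout aortas the range was 25 (without young knockout replicate 1) to 134 (without young knockout replicate 3), with 26 without young knockout replicate 2, 28 and 29 without aged knockout replicates 2 and 3 and 50 without young MR-intact replicate 1. The others were 141 to 187 averaged, 0 to 0 for knockout in young, 0 (without aged MR-intact replicate 2, 3 or 4 or aged knockout replicate 2 or 3) to 11 (without aged knockout replicate 1) in aged, 0 to 4 averaged (1 without young knockout replicate 2) and 0 to 4 for the interaction, where 4 was without aged knockout replicate 1. Lists ranged from 2 (without young knockout replicate 2) to 6. The correlation of age effects ranged from 0.797 to 0.889, and that of age with knockout from -0.168 (without aged MR-intact replicate 2) to 0.242, with -0.0425 without aged knockout replicate 2.

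miR-155 with age in MR-intact aortas was -1.84 with quantile normalization, -3.75 over all probe sets (adjusted p = 0.0641), -3.88 without the doubted arrays (0.0522), and -3.88 to -3.65 with 1 array left out (adjusted p 6.72e-06 to 0.132; 9 of 13 lost). In knockout aortas it was 1.53 with quantile normalization and -3.07 (adjusted p = 8.56e-05, without aged knockout replicate 1) to -0.065. Averaged it was -0.15, -2.48 and -2.24 in those 3 settings and -3.41 to -1.91 with 1 array left out, lost in 12 of 13 and kept without aged knockout replicate 1. For knockout it ranged from -0.44 to -0.23 in young, 0.33 to 3.34 in aged, -0.01 (-0.0117, without aged knockout replicate 1) to 1.49 averaged and 0.68 to 3.69 for the interaction.

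Quantile normalization turned miR-466e-3p (0.12) and miR-29b (0.017) in MR-intact, miR-98 (0.29), miR-21 (0.042) and miR-29b (0.040) in knockout, and miR-31-star (0.046), miR-138 (0.12), miR-18a (0.46), miR-98 (0.14), miR-466e-3p (0.046) and miR-29b (0.028) averaged. miR-126-3p turned to -0.105 in knockout without the doubted arrays and to 0.021 averaged after median centring. With 1 array left out it was -0.10 (without young knockout replicate 3) to 0.335 in knockout, with -0.005 without aged knockout replicate 3, and -0.21 to 0.03 (without aged MR-intact replicate 4) averaged, with 0.0071 without aged knockout replicate 1. miR-29b in knockout was -0.46 to 0.105 (without young knockout replicate 1).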

Other observations

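Both tests in this part had their reading set after their result was seen. Members of the Dlk1-Dio3 cluster may fall with age more often than other miRNAs of like level in young aortas. Of its 16 members above 2 in young aortas 87.5% fell, against 55.8% of 215 others, an odds ratio of 2.78 over 4 classes of level (exact p = 0.0144, and 0.115 adjusted over the 16 lists). The adjustment was added after the unadjusted p was seen, and by it the question stays open. The let-7 family had an odds ratio of 6.01 (exact p = 0.0053, adjusted 0.0848). Both p-values count miRNAs as independent, although members of a cluster or family are not, and do not measure the spread between samples.

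The fall of miR-1, miR-133a, miR-133b and miR-206 could come from uneven carry-over of skeletal muscle. Within groups the 4 correlated at a mean r of 0.207, and 0.551 of 10000 random quadruples of like level were as high, with a median of 0.241. By the rule first written, a mean below that median spoke against carry-over; the bound was moved after the value was seen, because 0.207 lay well inside the spread of the random quadruples, and the question stays open. No biological explanation was tested.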
